A study of Mus musculus with 16 samples.

How the data were processed

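Total RNA from control tissue and from the site of a B16 graft was hybridised, per the labels' protocols, to Illumina bead arrays after tissue lysis, Trizol extraction, column clean-up with DNase treatment and biotin labelling of cRNA. B16 is a pigmented melanoma cell line of C57BL/6 mice. The samples fall into 3 groups by their labels: control tissue with 7 arrays, tumor microenvironment at day 4 after inoculation with 4 arrays, and tumor microenvironment at day 14 with 5 arrays. The labels number the replicates and do not say which tissue the control was, whether each number was a separate mouse, or which slide held which array. P-values therefore measure the spread between these samples, part of which may be technical. No slide block was fitted, because no slide is given in the sources used here.

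A scanner table and a value table of the same 16 arrays were used. Per the file headers, the scanner table gives 1 signal and 1 detection p-value per probe and array. The deposited signals are intensity values on a linear scale with no background subtracted, as judged from the values, since none was at or below 0 and the medians ranged from 105 to 155 between arrays. The software that made them is not given in the sources used here. The scanner table has 45272 lines, of which 42831 carry a probe ID and signals and 2441 carry detection p-values alone. From a line near the top on, the deposited detection p-values stand 2441 lines below the signal they belong to. As printed, p and signal had a Spearman correlation near 0 on each array, and with the shift removed p fell with the signal on each of the 16 arrays with 0 reversals (Spearman correlation -0.97 to -0.99). The shift was removed before any use of p. The 2441 lines without an ID were left out of all comparisons.

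The deposited value table holds log2 values of 16247 probes, with array medians of 8.51 to 8.57. How the authors made it is not given in the sources used here. On each array its values rank the probes as the scanner signals do (Spearman correlation 1), the arrays have near-equal quartiles, and genes are not centred. It served as an alternative. Of its probes, 14836 have 1 gene symbol in the platform annotation used, 5 have several and 1406 have none listed. Symbols were updated by gene ID for 14830 probes. Because the symbols cover only the probes of the value table, a probe outside it is unnamed here, and 8557 detected probes without a symbol were tested separately by probe.

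Signals were background-corrected with normexp from the detection p-values, given an offset of 16, quantile normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3. A probe was kept with a detection p under 0.05 on at least 4 arrays, which left 14121 of the 14124 probes with a signal and 1 symbol. The probe with the highest mean over all arrays stood for each symbol, which gave 9450 genes. One limma model (lmFit and eBayes) held the 3 groups over all 16 arrays. Its tests are two-sided, adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05 and at least 2-fold. Detected probes numbered 15555 to 21669 per array. The number of arrays per group limits the precision, and the median standard error of a log2 difference was 0.347 for day 4 against control, 0.324 for day 14 against control and 0.372 for day 14 against day 4.

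Of 33 gene lists for cell types and processes fixed before the data were examined, 29 had at least 5 tested members. The hair follicle, B cell, erythrocyte and lymph node stroma lists had fewer and were not analysed here as lists. Some genes are in several lists, and most markers of a host cell type are also expressed in normal skin or muscle. The lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg over all lists and the 3 comparisons together. Camera with a correlation estimated per list and fry were run beside it. The list test was tried on simulated arrays with independent genes, where it called the 1 list raised 2-fold and gave 8 of 200 unchanged lists a p under 0.05, which does not test it on genes that vary together as they do here. The model was tested on simulated data too. With the residuals of the real arrays shuffled as whole arrays over 9450 genes, the model recovered 30% of 50 genes changed 2-fold, 76% of 50 changed 4-fold and 88% of 50 changed 8-fold for day 4 against control, and 38%, 76% and 86% for day 14 against control, with 0 false calls in both. With the SD of each gene and independent genes, it recovered 18%, 74% and 88% for day 4 with 2 false calls, and 24%, 72% and 92% for day 14 with 5 false calls. Each setting was drawn 1 time and used for both comparisons. The counts of false calls therefore give no rate, least of all for genes that vary together. The changed genes were drawn at random from all genes, so the shares recovered do not hold for tissue genes, whose standard errors were larger. Acta1 at day 14 had a standard error of 1.83, against the median of 0.324, and was not called at a log2 difference of -4.06. The shuffled residuals were not scaled up for the fitted group means, so their spread was somewhat too small.

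The rules for naming genes were fixed in advance: the 8 called genes with the largest changes each way, the 3 called members of each list each way, members not called where their number is given, 5 genes per time class, and 15 genes whatever their result. Since 0 genes were called, the rules on called genes named none. No rule fixed which uncalled members to name, so those given beyond the 15 are examples. Of those 15, Cd8a, Gzmb, Ifng, Mki67 and Cd68 have no named probe here and were not analysed here. Alternatives covered the background correction, the scaling between arrays, the detection filter, the probe rule, the variance model, array weights, the groups in the fit, the thresholds, the value table, the replicate number as a block, the list test, and each array left out in turn. Fits without 3 tumor arrays, without these and control array 1 or day 4 array 1, and the list test with an estimated correlation without the 3 arrays, were added after the data were seen.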

Results

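The series measured transcripts in control tissue and in the B16 melanoma graft site of C57BL/6 mice at day 4 and at day 14 after inoculation, to show how the tissue around a tumor changes with time. The 16 arrays comprised 7 controls, 4 of day 4 and 5 of day 14. Control arrays detected 20350 ± 549 probes (SD, n = 7), day 4 arrays 19178 ± 2354 (SD, n = 4) and day 14 arrays 18551 ± 2441 (SD, n = 5).

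The arrays differed more within the groups than between them. The first principal component held 71.9% of the variance. It set 3 tumor arrays (day 4 array 4 and day 14 arrays 2 and 5), with scores of 143, 143 and 147, apart from the other 13, whose highest score was 27. On these 3 arrays 17, 21 and 12 of 96 genes from the epidermis, skeletal muscle, adipocyte, fibroblast, endothelial and macrophage lists were detected, against at least 89 on each other array. They correlated at 0.964 to 0.979 with each other and at most at 0.789 with any other array. Melanocyte transcripts were present on control arrays too. The mean of the 16 tested melanocyte and pigmentation genes was 6.60 on control array 1 and 9.30 to 12.06 on the other 6 control arrays, against 8.59 to 12.10 on the 9 tumor arrays. The group labels held 20.6% of the sum of squares, and a permutation test of the labels over 100000 permutations gave p = 0.166. Only 2 of the 16 arrays, control arrays 2 and 3, had an array of their own group as the most similar one.

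**Figure D1:**
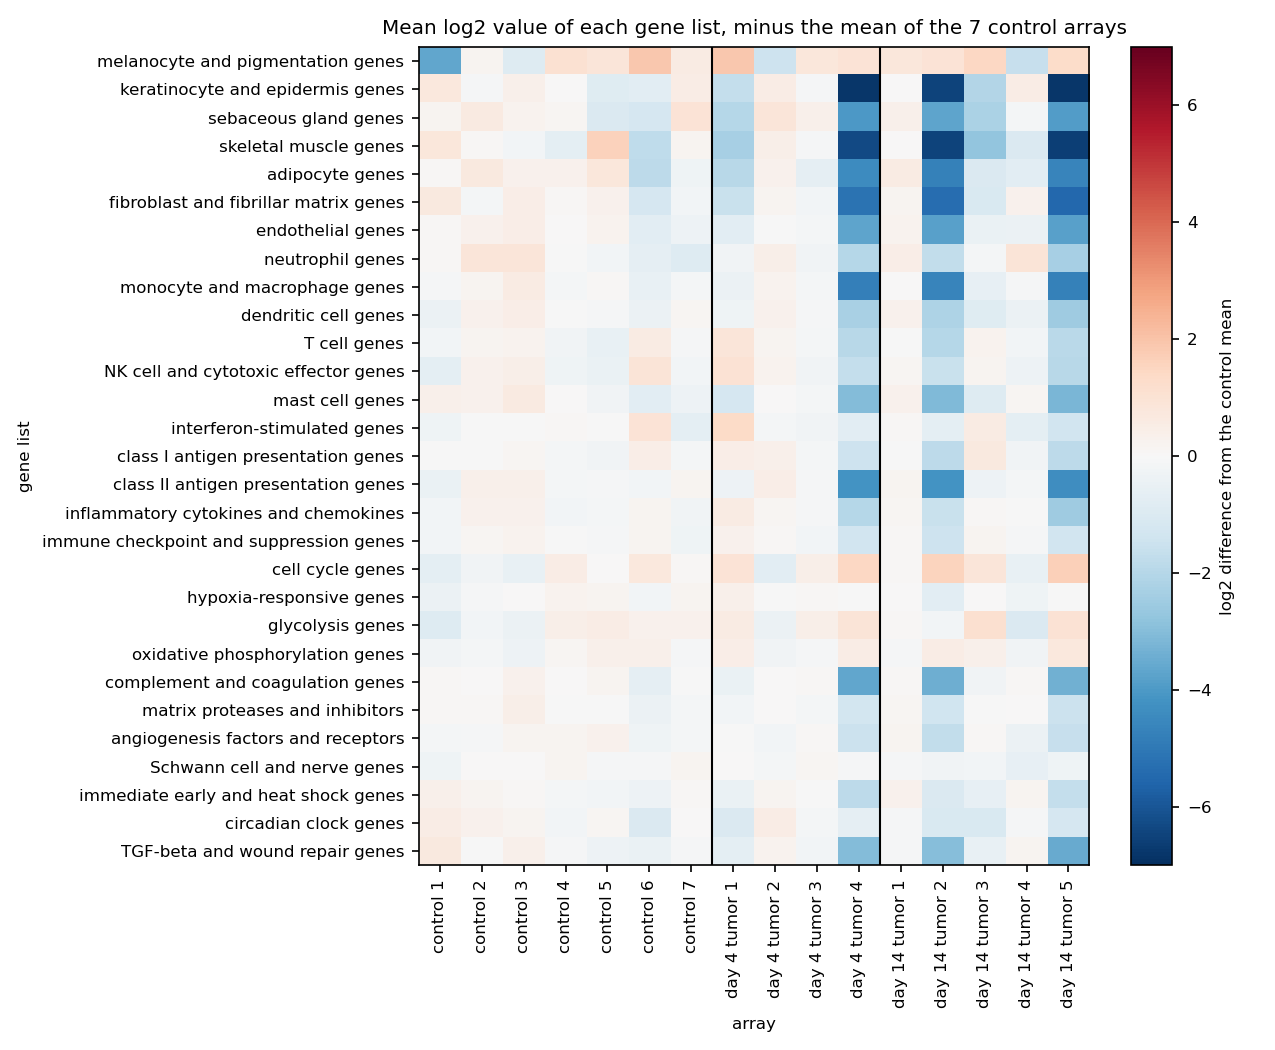
Heat map of the mean log2 signal of 29 gene lists on each of the 16 arrays, minus the mean of the 7 control arrays; red is above and blue below the control mean. Day 4 array 4 and day 14 arrays 2 and 5 stand out in the tissue lists, and control array 1 in the melanocyte list.

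The comparison of day 4 with control asks what the graft site holds early after inoculation. Lists of differentiated tissue were lower as groups by camera. The 19 skeletal muscle genes had a mean log2 difference of -2.06 (adjusted p = 1.46e-07), the 19 fibroblast and fibrillar matrix genes -1.70 (adjusted p = 3.57e-07), the 16 keratinocyte and epidermis genes -2 (adjusted p = 1.15e-05), and the 9 adipocyte genes -1.67 (adjusted p = 6.21e-05). The 21 monocyte and macrophage genes were lower by a mean log2 difference of -1.28 (adjusted p = 5.43e-06) and the 12 endothelial genes by -1.16 (adjusted p = 4.27e-05). The 25 cell cycle genes were higher as a group, with a mean log2 difference of 0.53 (adjusted p = 6.21e-05) and a positive difference in each of the 25. The correlation estimated from these arrays was 0.82 to 0.9 in these 7 lists, far above the preset 0.01, so the adjusted p-values above are too small. With an estimated correlation, each of these 7 lists had an adjusted p = 0.7, and no list passed with it or with fry in any of the 3 comparisons. Day 4 array 4, on which 17 of the 96 tissue genes were detected, enters each of these means.

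None of the members of these lists was called at day 4 over all genes, and 0 were called when adjusted over the list alone. Krt14, a basal keratin of the epidermis, had a log2 signal of 11.81 ± 4.91 (SD, n = 4) at day 4 and 14.35 ± 0.12 (SD, n = 7) in controls. Its log2 difference was -2.54 with a standard error of 2.06 (adjusted p = 0.75). For Acta1, the skeletal muscle actin, the difference was -2.70 with a standard error of 1.96, and for Col1a1, a chain of type I collagen, -2.91 with a standard error of 1.95. Among uncalled macrophage genes, the differences were -1.65 for Csf1r, the receptor of macrophage growth factor, and -1.95 for Lyz2, a lysozyme. Of the pigment genes, Dct differed by 0.65 with a standard error of 0.94 and Tyr, the rate-limiting enzyme of melanin synthesis, by 0.95 with a standard error of 1.20. Without control array 1 the difference was -0.21 for Dct and 0.392 for Tyr. The melanocyte list, with 0 of 16 members called, had a mean difference of 0.565 and did not pass (adjusted p = 0.101). Without control array 1 this mean was -0.0365. At the preset correlation the list passed upward without control arrays 4 (0.743), 5 (0.709), 6 (0.874) or 7 (0.662), or without day 4 array 2 (1.23). The fits without a single array were not run with an estimated correlation.

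Of the lists that passed in this comparison, 10 remain. Their mean log2 difference was -1.21 for sebaceous gland, -1.09 for mast cell, -1.03 for class II antigen presentation, -1 for complement and coagulation, -0.91 for TGF-beta and wound repair, -0.59 for dendritic cell, -0.54 for immediate early and heat shock, and -0.40 for matrix protease genes. It was 0.35 for glycolysis and 0.19 for oxidative phosphorylation genes. Their adjusted p lay between 0.0025 and 0.0478, and between 0.7 and 0.718 with an estimated correlation. The T cell list (mean -0.255, adjusted p = 0.425) and the interferon-stimulated list (mean 0.04, median -0.01, adjusted p = 0.632) did not pass.

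No gene was called at day 4 by limma, over 9450 genes. The lowest adjusted p was 0.75, and 56 genes had an unadjusted p under 0.05, 36 higher and 20 lower, where 472 would be expected by chance with independent genes. Without the 3 tumor arrays set apart above, chosen after the data were seen, the lists passing downward went from 14 to 6, with the muscle mean at -0.645, matrix -0.536, epidermis -0.401, endothelial -0.313, adipocyte -0.756 and mast cell -0.438, and the cell cycle list (0.225), the T cell list (0.307) and the interferon-stimulated list (0.308) passed upward at the preset correlation, each of these 9 lists with an adjusted p = 0.907 with an estimated correlation. Without day 4 array 1 as well, which leaves 2 day 4 arrays, none of the 6 tissue lists passed (muscle mean 0.185, matrix -0.0319), the T cell list (0.0388) and the cell cycle list (-0.168) did not pass, and the interferon-stimulated list passed downward (-0.199).

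The comparison of day 14 with control asks what the established tumor site holds. The same tissue lists were lower as groups, with larger mean differences. The skeletal muscle list had a mean log2 difference of -3.32 (adjusted p = 4.38e-08), the epidermis list -2.94 (adjusted p = 2.26e-05), the fibroblast and matrix list -2.30 (adjusted p = 5.43e-06), the adipocyte list -2.10 (adjusted p = 0.00091), the macrophage list -1.99 (adjusted p = 1.84e-06), the class II list -1.78 (adjusted p = 0.000779) and the endothelial list -1.65 (adjusted p = 0.000197). The cell cycle list was higher by 0.75 (adjusted p = 2.66e-05), with each of its 25 members above the control mean. With an estimated correlation each of these 8 lists had an adjusted p = 0.7. Day 14 arrays 2 and 5, with 21 and 12 of the 96 tissue genes detected, enter each of these means.

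All 19 skeletal muscle genes passed at day 14 when adjusted over the list alone, with 0 of them called over all genes. Examples are Ttn, the giant sarcomere spring protein (-4.20, standard error 1.55, the most negative of 6 probes, which ranged up to -1.04), Acta1 (-4.06, standard error 1.83) and Ckm, the muscle creatine kinase (-3.81, standard error 1.57). All 19 had an adjusted p of 0.269 over all genes. In the epidermis list 0 of 16 members were called either way, and Krt14 differed by -3.61 with a standard error of 1.92 (adjusted p = 0.279). In the matrix list 0 of 19 were called, and Col1a1 differed by -3.67 with a standard error of 1.82 (adjusted p = 0.27). Of the 21 macrophage genes 0 were called. Among them Arg1, an arginase of suppressive macrophages, differed by -1.27 with a standard error of 1.23. Without the 3 tumor arrays, on which Arg1 was not detected, its log2 difference turned to 1.06. C1qb, a complement subunit, differed by -3.30 with a standard error of 1.70. Of the 25 cell cycle genes 0 were called, with Cdk1, the mitotic kinase, at 1.115 (standard error 0.472) and Birc5 at 1.03 (standard error 0.531).

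**Figure D2:**
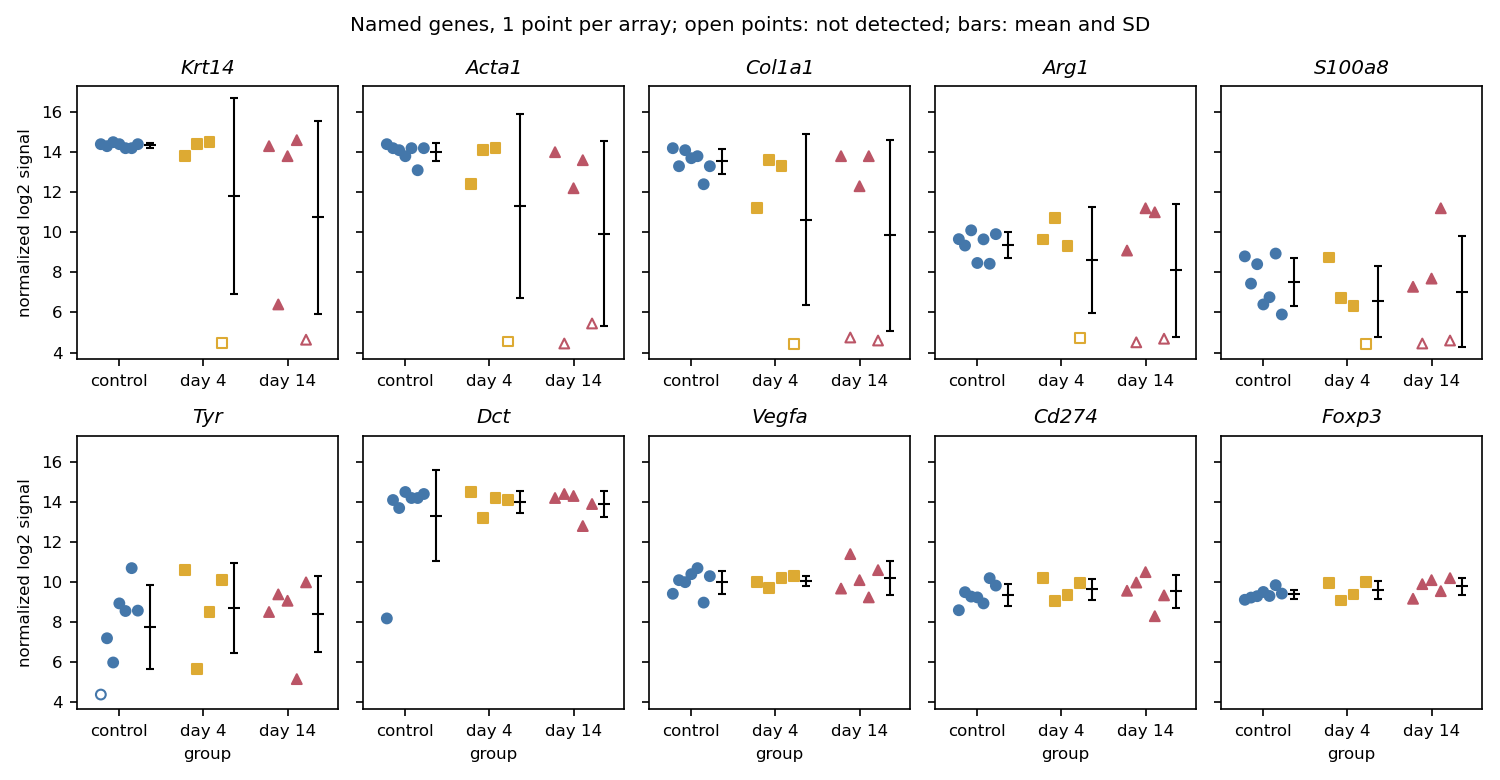
Normalized log2 signal of 10 named genes, with 1 point per array (controls as circles, day 4 as squares, day 14 as triangles), open points where the probe was not detected, and bars for the mean and SD of each group. Krt14 in controls lies at 14.35 ± 0.12 (SD, n = 7), while day 14 splits into arrays near 14 and 2 arrays at 6.4 and 4.6.

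No gene of the tumor cells or of immune regulation fixed in advance passed at day 14. Dct was 13.91 ± 0.63 (SD, n = 5) at day 14 and 13.34 ± 2.29 (SD, n = 7) in controls (difference 0.58, standard error 0.877, adjusted p = 0.662), and without control array 1, at 8.19, the difference was -0.28. For Tyr the difference was 0.66 with a standard error of 1.12, and 0.0971 without that array. Foxp3, the factor of regulatory T cells, differed by 0.38 (standard error 0.224, adjusted p = 0.296) with its brighter probe and by -0.503 with its other probe. The brighter probe was detected on all 16 arrays. These include the 3 tumor arrays set apart above, on which 2 or 3 of the 13 T cell genes were detected, so it may not follow T cells here. Cd274, the PD-L1 ligand, differed by 0.16 (standard error 0.359), Vegfa by 0.21 (standard error 0.355) and S100a8, a neutrophil calgranulin, by -0.48 (standard error 1.05). The melanocyte list had a mean difference of 0.59 and a median of 0.83 (adjusted p = 0.142), with 14 of 16 members above the control mean. Without control array 1 the mean difference was -0.014, and without day 14 array 4 it was 1.14 and the list passed upward by camera at the preset correlation (adjusted p = 0.024). Of the lists passing at day 14, 7 remain. Their mean log2 difference was -1.91 for sebaceous gland, -1.38 for TGF-beta and wound repair, -1.34 for mast cell, -1.12 for dendritic cell, -0.77 for inflammatory cytokine, -0.69 for circadian clock and 0.26 for oxidative phosphorylation genes, with adjusted p from 0.00146 to 0.0382, and 0.7 to 0.718 with an estimated correlation. The T cell list (mean -0.78, adjusted p = 0.0795) and the interferon-stimulated list (mean -0.41, adjusted p = 0.118) did not pass. In the hypoxia list, which did not pass (mean -0.21, adjusted p = 0.644), 1 of 16 genes passed when adjusted over the list alone and 0 over all genes, the stress-response gene Ddit4 at 1.24 (standard error 0.324, adjusted p = 0.269 over all genes).

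No gene was called at day 14 by limma. The lowest adjusted p was 0.269, shared by many genes, and 1703 of 9450 genes had an unadjusted p under 0.05, 585 higher and 1118 lower. Without the 3 tumor arrays this number was 204 and the lists passing downward went from 13 to 1, the skeletal muscle list, at a mean log2 difference of -1.20 (adjusted p = 0.907 with an estimated correlation). Upward they went from 2 to 0, with the cell cycle list at 0.168.

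The comparison of day 14 with day 4 asks how the site changes as the tumor grows. Lymphoid and antigen-presentation lists were lower at day 14 by camera: the interferon-stimulated genes by a mean log2 difference of -0.45 (adjusted p = 0.000675), the dendritic cell genes by -0.53 (adjusted p = 0.00225), the class II genes by -0.755 (adjusted p = 0.0147), the NK and cytotoxic genes by -0.56 (adjusted p = 0.0217), the T cell genes by -0.52 (adjusted p = 0.0289) and the class I genes by -0.43 (adjusted p = 0.0289). The skeletal muscle list (-1.26, adjusted p = 0.000244), the macrophage list (-0.70, adjusted p = 0.00345), the circadian clock list (-0.38, adjusted p = 0.0255), the cytokine list (-0.42, adjusted p = 0.0289), the epidermis list (-0.94, adjusted p = 0.0316) and the hypoxia list (-0.31, adjusted p = 0.0372) were lower too. The cell cycle list was higher by 0.22 (adjusted p = 0.0141), with 22 of 25 members higher. With an estimated correlation these 13 lists had adjusted p from 0.7 to 0.718. One of 4 day 4 arrays and 2 of 5 day 14 arrays had few tissue genes detected.

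Of the 23 interferon-stimulated genes 0 were called, with Irf7, a regulator of interferon genes, at -1.25 (standard error 0.665) and Cxcl10, a T cell chemokine, at 0.08 (standard error 0.988). Of the 13 T cell genes 0 were called, with Cd3e, a chain of the T cell receptor complex, at -1.09 (standard error 0.786) and Foxp3 at 0.16 (standard error 0.257), or -0.372 with its other probe. Of the 12 class II genes 0 were called, with H2-Aa at -1.185 (standard error 1.56) and Cd74, the invariant chain, at -1.23 (standard error 1.68). Of the 16 hypoxia genes 0 were called, with Car9 at -0.89 (standard error 0.938, the 3 probes from -0.886 to -0.144) and Vegfa at 0.15 (standard error 0.407), or -0.00514 with its other probe. Krt14 differed by -1.07 (standard error 2.20) and Acta1 by -1.35 (standard error 2.09). Dct, at -0.07 (standard error 1.00), and Tyr, at -0.29 (standard error 1.28), differed by less than their errors.

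No gene was called between the days by limma. The lowest adjusted p was 1, and 57 genes had an unadjusted p under 0.05, 19 higher and 38 lower. Without the 3 tumor arrays, of the 12 lists passing downward only 1 list passed, the interferon-stimulated genes (-0.32), and the fibroblast and matrix list passed upward at 0.31. With an estimated correlation neither list passed. Without day 4 array 1 as well, neither passed at the preset correlation and the interferon-stimulated mean was 0.186. Without the 3 tumor arrays alone the cell cycle list turned (-0.0567), as it did without day 4 array 2 (-0.209), and it did not pass without day 14 arrays 2, 3 or 5 (0.0185, 0.18 and -0.0207). The epidermis list was at -0.0797 without the 3 arrays, at -0.0827 without day 4 array 2, and at -0.058 and 0.0196 without day 14 arrays 2 or 5, and passed in none of these. With single arrays left out, the interferon-stimulated mean ranged from -0.717 to -0.024, with -0.024 without day 4 array 1, and it did not pass without that array or without day 14 arrays 4 or 5. Each other list that passed between the days also failed without at least 1 single array. The T cell (-0.157), NK and cytotoxic (-0.173) and class I lists (-0.215) failed without day 4 array 1. The muscle (-0.431) and circadian clock lists (-0.103) failed without day 4 array 2, and the macrophage list (-0.0173) without day 14 array 5.

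With 0 genes called in either comparison with control, the overlap of called genes was 0 and every time course class held 0 genes. Over the 9450 genes the log2 differences of both days from control correlated at 0.944, a correlation across genes, which are not independent replicates. Both share the 7 controls. Unchanged groups simulated against these controls gave a median correlation of 0.442 (95% range -0.729 to 0.943). With odd-numbered controls for one day and even-numbered ones for the other, the correlation was 0.768, and 0.777 the other way round. It was 0.645 without day 4 array 4, 0.598 with array weights, 0.592 without the 3 tumor arrays, 0.497 without these and control array 1, and -0.133 without these and day 4 array 1. The covariance was 0.528, against a simulated median of 0.0605 (95% range -0.222 to 0.62), so it lay within the simulated range. The correlation of 0.944 lay just above the upper limit of its range. Because residuals of the tumor arrays also entered the simulated controls, neither value decides whether both days share a change.

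**Figure D3:**
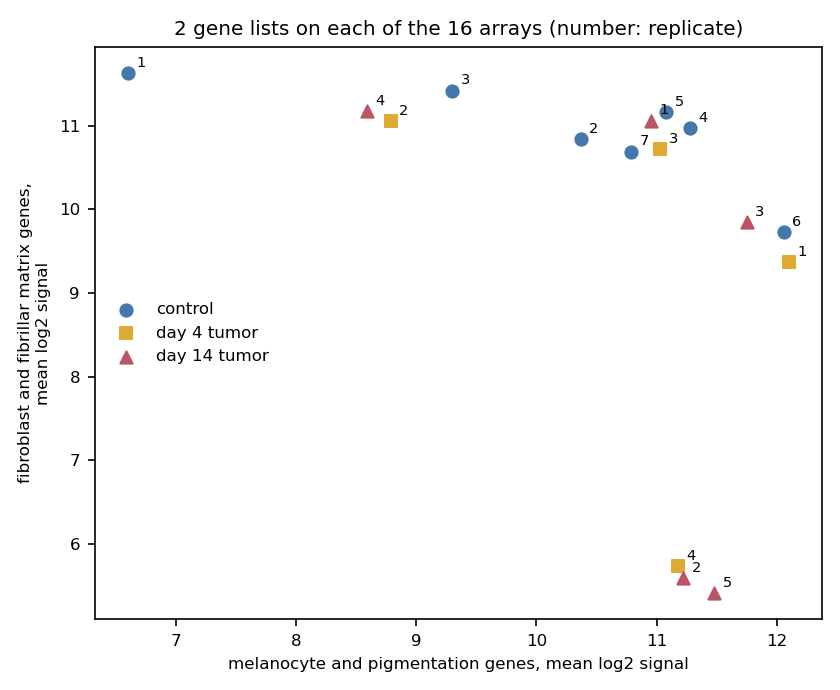
Mean log2 signal of the 19 fibroblast and fibrillar matrix genes (vertical axis) against that of the 16 melanocyte and pigmentation genes (horizontal axis) on each of the 16 arrays, labelled by replicate number. Day 4 array 4 and day 14 arrays 2 and 5 lie at 5.41 to 5.73 on the vertical axis and the other 13 arrays at 9.37 to 11.63, and control array 1 lies at 6.60 on the horizontal axis.

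Several symbols were measured by more than 1 probe, and the value given is that of the brightest unless another probe is named. Probes without a symbol gave the same outcome, with 0 of 8557 called in each comparison and 90, 1014 and 98 at an unadjusted p under 0.05.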

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

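All tests of explanations in this part were chosen after the result was seen, except the splits counted for lists and for unadjusted p. Of 120 sets of values tested for a sample far from the others of its group (10 named genes, 29 lists and the number of probes detected, in 3 groups), 8 stood out, where chance gives about 6. Each ratio below is the gap to the nearest array over the range of the group. In this ratio 2 low arrays of a group hide each other. Day 14 arrays 2 and 5 were therefore not flagged in the tissue lists (macrophage means 4.78 and 4.66, against 8.81 to 9.44 on the other day 14 arrays). The count of 8 thus does not cover them. Krt14 was 4.47 on day 4 array 4 and 13.8 to 14.5 on the other day 4 arrays (ratio 0.927), and the macrophage list mean was 4.61 against 8.96 to 9.61 (0.871) and the complement and coagulation mean 5.27 against 8.48 to 9 (0.859). Dct was 8.19 on control array 1 and 13.7 to 14.5 on the other controls (0.867). On control array 6 the adipocyte mean was 8.18 against 9.72 to 10.8 (0.588) and the complement mean 8.27 against 8.90 to 9.25 (0.643). On day 14 array 4 Dct was 12.8 against 13.9 to 14.4 (0.711) and the melanocyte mean 8.59 against 11 to 11.7 (0.747).

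The first pattern is that 3 tumor arrays, 1 of day 4 and 2 of day 14, detected few tissue genes. A failed or dim hybridisation would lower other genes too, yet all 50 cell cycle and oxidative phosphorylation genes were detected on each. The normalization between arrays cannot be the source, since detection calls precede it, and they showed at most 21.9% of the 96 tissue genes on these arrays against at least 92.7% on the other 13. Nearly pure tumor cells would have the highest cell cycle means, which these arrays had (lowest 10.58 against at most 10.14 elsewhere). The highest melanocyte means were also looked for, which these arrays had not (11.18 to 11.48, against 12.06 on control array 6, 12.10 on day 4 array 1 and 11.75 on day 14 array 3). The melanocyte part cannot decide, because Krt27, Krt33a and Krt71 were at 12.54 to 14.35 on those 3 other arrays. Melanocytes of hair follicles may add to their means, although day 14 array 4, with these keratins at 14.35 to 14.64, had a melanocyte mean of 8.59. Whether the arrays low in tissue genes were nearly pure tumor or samples of another kind, such as cultured cells, cannot be told apart, because their correlation of 0.964 or more with each other has no reference of cultured cells to be set against.

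The second pattern is that melanocyte transcripts were high on 6 of 7 control arrays. Melanocytes of growing hair follicles would bring hair keratins, and Krt27, Krt33a and Krt71 were at most 5.17 on control arrays 5 and 7, which argues against it there, while they reached 9.12 on control arrays 2 to 4 and all 3 were over 10 on control array 6, where it stays open. Labels exchanged for all 6 would need 6 tumor arrays below these controls, and 2 of 9 were, day 4 array 2 (8.79, most similar to control array 3) and day 14 array 4 (8.59), so an exchange of single samples cannot be told apart from other sources. Tumor cells or their RNA in the control samples may account for it: over the 7 control arrays the melanocyte mean went with the cell cycle mean (Spearman rho 0.964, exact permutation p = 0.00278, Pearson r = 0.877, exact permutation p = 0.00258, adjusted over 3 relations 0.00833 and 0.00774, r = 0.938 without control arrays 1 and 3, and rho 0.943 without control array 6, whose melanocyte mean lay above those of the 3 tumor arrays). Control arrays 4 and 6, with the highest cell cycle means of the controls (9.65 and 9.88), also had the highest Krt27 (9.12 and 14.18). On these arrays the relation therefore does not separate tumor cells from hair follicles. A wrong label on single control samples stays open, and no other explanation was tested.

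The third pattern is the fall of tissue lists against control. At day 14, 1 of 13 lists still passed downward without the 3 arrays, skeletal muscle (-3.32 with them, -1.20 without), so these arrays may carry most of that result, the cell cycle list included (0.75 with them, 0.168 without). At day 4, 6 of 14 lists did, with smaller means: muscle from -2.06 to -0.645, matrix from -1.70 to -0.536, epidermis from -2 to -0.401 and endothelial from -1.16 to -0.313. Day 4 array 4 may thus carry most of the size of these differences, and none of the 6 lists passed without day 4 array 1 as well (muscle 0.185, matrix -0.0319, epidermis 0.245), with 2 day 4 arrays left. With an estimated correlation, no list passed at either day without the 3 arrays. A change of the tissue around the tumor with time, which the design names, stays open: without the 3 arrays limma called 0 genes in each comparison, with 13, 204 and 100 at an unadjusted p under 0.05 (day 4 and day 14 against control, and between the days).

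Between the days, 13 lists passed camera's test of the difference, all lost with an estimated correlation. Their mean log2 differences, day 14 minus day 4, were -1.26 (skeletal muscle), -0.941 (epidermis), -0.755 (class II), -0.703 (macrophage), -0.556 (NK and cytotoxic), -0.528 (dendritic cell), -0.523 (T cell), -0.451 (interferon-stimulated), -0.428 (class I), -0.423 (cytokine), -0.376 (circadian clock), -0.306 (hypoxia) and 0.218 (cell cycle). Among the 2441 lines with detection p-values and no probe ID, 4 were detected on at least 4 tumor arrays and on no control array, and 0 the other way round.

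Other splits of the samples into groups of the same sizes, 100 per comparison with the real one, do not exclude chance for the lists or for the genes at an unadjusted p. For the genes called they say nothing, because with a real count of 0 all 100 of 100 splits reach it. The highest other count was 0 for both comparisons with control and 3300 for day 14 against day 4, a split that points to a structure of the samples other than the labels. As many lists came from 27 of 100 splits at day 4 (real 17, highest other 22), 57 of 100 at day 14 (real 15, highest other 26) and 67 of 100 between the days (real 13, highest other 23). The 1703 genes at an unadjusted p under 0.05 at day 14 were reached by 7 of 100 splits (highest other 4113).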

How the results depend on the processing

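The 4 settings that leave out several arrays together were chosen after the data were seen, and the other alternatives before the data were examined. The counts of genes called (0 in each direction and comparison, at both days and in each time course class) stayed at 0 under every alternative run, and none of the 10 tested named genes was called under any, although 79 of their 870 values changed sign without a call on either side. The slide as a block was not run, and the thresholds on genes do not apply to lists. The cause of the changes below was not tested, except that fewer arrays enter when arrays are left out and that the estimated correlation replaces the preset one. The estimates were 0.82 to 0.9 for the muscle, matrix, epidermis, adipocyte, macrophage, endothelial and cell cycle lists, against the preset 0.01.

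List counts at the preset correlation were 14 down and 3 up (day 4 against control), 13 and 2 (day 14 against control) and 12 and 1 (day 14 against day 4). With an estimated correlation all 6 counts were 0, and with fry 0. Median scaling gave 6 down and 2 up for day 14 against day 4. Array weights gave 2 down and 1 up at day 4 and 0 up for day 14 against day 4, where the interferon-stimulated list turned, at a mean log2 difference of -0.01 (-0.0136). A list's direction is relative to the other genes, so it can turn while its mean stays below 0.

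No pairing by replicate number was seen. Over 13 pairs with the same number the deviations from the group means correlated at a median of 0.056 (-0.81 to 0.45). Over 70 pairs with different numbers the median was 0.023 (-0.88 to 0.93). The large differences in tissue transcripts between arrays could hide a pairing, so it is not excluded. With the replicate block, 0 genes were called, and 6 lists passed downward and 0 upward for day 14 against day 4.

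Without the 3 tumor arrays low in tissue genes, 6 lists passed downward at day 4, 1 downward and 0 upward at day 14, and 1 downward between the days. Directions turned at day 4 for the T cell (0.307), class II (0.0225) and dendritic cell lists (-0.0227), at day 14 for the cytokine list (0.0654), and between the days for the fibroblast and matrix (0.311), cell cycle (-0.0567), class I (-0.0504) and epidermis lists (-0.0797). Without control array 1 as well, 5 lists passed downward at day 4, 1 downward and 0 upward at day 14, and 1 downward between the days. Turned were the T cell list at day 4 (0.274), the cytokine (0.0352), mast cell (-0.0847) and TGF-beta lists (-0.00902) at day 14, and the fibroblast and matrix (0.311), cell cycle (-0.0567), class I (-0.0504) and epidermis lists (-0.0797) between the days. Of these, the T cell and matrix lists passed in their new direction. The interferon-stimulated list gained an upward call at day 4 (0.308, and 0.259 without control array 1 as well). With an estimated correlation and without the 3 arrays, all 6 counts were 0.

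Without the 3 tumor arrays and day 4 array 1, lists passing downward and upward numbered 2 and 2 at day 4, 1 and 0 at day 14, and 4 and 2 between the days, and the correlation of both days' log2 differences turned to -0.133. Turned at day 4 and passing were the class II (0.213), interferon-stimulated (-0.199), oxidative phosphorylation (-0.157) and sebaceous gland lists (0.587). Turned at day 4 without passing were the muscle (0.185), epidermis (0.245), matrix (-0.0319), macrophage (0.0364), dendritic cell (0.106), complement (0.0516), immediate early (0.0817), TGF-beta (0.0392), cell cycle (-0.168) and glycolysis lists (-0.0462). At day 14 the cytokine list turned (0.0654), and between the days the T cell (-0.0476), class I (0.0659), cytokine (0.0433) and interferon-stimulated lists (0.186).

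With each array left out in turn, lists passing downward numbered 6 to 19 at day 4, 10 to 21 at day 14 and 1 to 17 between the days, and upward 1 to 4, 1 to 3 and 0 to 3. The downward count moved by over 1.5 times at day 4 without day 4 array 4 (6), at day 14 without day 14 array 3 (21), and between the days without day 4 arrays 1 (4), 2 (3) and 3 (5) and day 14 arrays 2 (1) and 5 (2). The upward count did so at day 4 without control arrays 1, 2 or 3, day 4 array 1 or day 14 array 2 (1 each), at day 14 without control array 3 or day 14 arrays 3 or 5 (1 each), and between the days without day 4 arrays 1 or 4 (2 each), day 14 arrays 2 or 3 (0 each) or day 14 array 4 (3). Lists that turned in 1 or more of the fits without a single array ranged from -0.384 to 0.308 (interferon-stimulated, day 4, called down without day 4 array 1), -0.621 to 0.307 (T cell, day 4), -0.875 to -0.0227 (dendritic cell, day 4), -0.209 to 0.529 (cell cycle, between the days), -2.54 to 0.0196 (epidermis, between the days) and -0.968 to 0.0058 (cytokine, between the days). The correlation of both days' log2 differences ranged from 0.645 to 0.952, with 0.645 without day 4 array 4. It was 0.598 with array weights, 0.592 without the 3 tumor arrays and 0.497 without these and control array 1. Over all list values and settings, 2296 of 2784 kept their side of the threshold, 358 lost it, 80 gained it and 50 turned. This total does not measure stability, because lists that did not pass in the main fit count as kept. With an estimated correlation, and with fry, 42 of 87 values kept their side although no list passed, and the other 45 lost it. Some settings hardly changed the input, such as no detection filter, where all 87 were kept. Signals near background limit the tissue genes on the 3 arrays, where most were not detected.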

Other observations

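All tests in this part were chosen after the result was seen. Keratins of the hair shaft and inner root sheath varied from near background to among the brightest probes, across all 3 groups. Krt71, a root sheath keratin, had a log2 signal of 14.35 on control array 6, 13.64 on day 4 array 1, and 13.54 and 14.64 on day 14 arrays 3 and 4, and 4.33 to 7.89 on the other 12 arrays. Krt27 was 13.91 to 14.48 and Krt33a 12.54 to 14.35 on the same 4 arrays. Of these, control array 6 and day 4 array 1 were each the most similar array of the other (correlation 0.98).

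Interferon-stimulated and T cell lists were highest on the same pair of arrays. The interferon-stimulated mean was 10.2 on day 4 array 1 and 9.8 on control array 6, and 7.5 to 9.4 on the other arrays. The T cell mean was 8.3 and 8.1 on this pair and at most 7.7 elsewhere. Over the 7 control arrays the melanocyte mean also went with the oxidative phosphorylation mean (Pearson r = 0.758, exact permutation p = 0.025, Spearman rho 0.929, exact permutation p = 0.00675, adjusted p 0.0375 and 0.0101, and r = 0.821 without control arrays 1 and 3). Its relation with the fibroblast and matrix mean did not pass (r = -0.764, exact permutation p = 0.0728, rho = -0.714, exact permutation p = 0.0881). The number of arrays whose most similar array carried the same label was 2, against a median of 5 over 100000 permutations of the labels (permutation p = 0.134 for 2 or fewer).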
